A study of Mus musculus with 40 samples.

How the data were processed

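RNA was extracted with TRI Reagent from the left ventricles of 10-week-old male and female mice, wildtype or with a knockout of Rbm20, and sequenced on a BGISEQ-500. The labels name 40 libraries, 2 from each of 20 mice, with 5 mice in each of the 4 groups of sex and genotype. Per the submitters' processing notes, the authors aligned the reads with STAR 2.7.10a to the mouse build GRCm39 and tested genes with DESeq2. The program that counted reads and the annotation release are not stated.

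The deposited gene tables, 1 per sex, hold a signal per library: read counts that the authors divided by a size factor of each library, as DESeq2 does. This was checked on the values. In every mapped library, 100% of the values were whole multiples of 1 step, to a tolerance of 1e-06 of a read, so the reads behind each value could be recovered. The size factors ranged from 0.326 to 2.34. The tables list 25462 genes for females and 24930 for males. The authors' log2 fold changes and their p-values in the same tables were used as an alternative test. The deposited exon tables hold raw counts per exon bin, a part of a gene that shares the same exons, with the authors' own p-values from DEXSeq, which tests whether a bin's share of its gene differs. Each exon table lists bins with an unadjusted p of at most 0.05, and the start and end it prints are those of the gene, so the position of a bin within its gene is not known here. The male exon bins are given in 2 tables that hold the same bins and adjusted p-values. Because the authors scaled each sex in its own table, levels were not tested between females and males, and the sex-linked genes were set side by side only as a check of the labels.

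Columns were matched to mice through the column numbers in the sample descriptions. One column of per-sample gene values in the female table matches no label and was not used here, so knockout female 154 is represented by 1 library and 39 libraries were used. The libraries held 2351987 to 16973229 reads in genes, with a median of 9043245. Whether the 2 libraries with 1 mouse number share their RNA was checked by the spread between them over genes with at least 20 summed reads. The chi-square per degree of freedom was 1.07 to 1.84 in 19 pairs of the same mouse, where 1 is counting noise, and 2.77 to 32.6 in 152 pairs of different mice of 1 group. The mouse was therefore the replicate, with n = 5 per group. This is an average over genes, and how counting error compares with the spread between mice near the filter was not tested.

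The value of a gene in a mouse was the mean of its libraries. Genes with a mean of at least 10 over the mice of a fit were tested on log2(value + 1) with limma 3.58.1 in R 4.3.3, with the trend of variance on mean, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Had the tables held counts, edgeR was the first choice. Since the deposited unit was normalized, limma was used, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads were run as alternatives. Knockout was compared with wildtype in each sex, and the difference between the sexes was the interaction: the knockout change in males minus that in females, in 1 fit of the 4 groups. In these differences a scale of each table cancels. The tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Others were chosen after seeing the data and are named where they are given.

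Genes named in the results are Rbm20. In each sex they are also the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 50, every knockout mouse on the same side of every wildtype mouse, and a symbol that is not a predicted or clone name. Up to 4 members of each list with the smallest p in that sex were added, as were the 10 genes with the smallest p for the difference between the sexes, the splicing targets and the 10 genes with the most exon bins in each sex, and 5 sex-linked genes as a check of the labels. Genes and bins named outside this rule are marked as chosen after their values were seen. Some genes that the rule names are not reported here.

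The 30 lists were RBM20 splicing targets, fetal and stress genes, sarcomere and Z-disc, calcium handling, ion channels and conduction, oxidative phosphorylation, mitochondrially encoded genes, fatty acid oxidation, glycolysis and glucose use, extracellular matrix and fibrosis, heat shock and unfolded protein response, integrated stress response and amino acid synthesis, immediate early genes, circadian clock, cell cycle, sex hormone receptors and targets, sex-linked genes and RNA-binding splicing factors. Lists of markers covered fibroblasts, endothelial cells, mural cells, macrophages and myeloid cells, lymphocytes, inflammation and interferon, atrium, red blood cells, adipocytes, neural and Schwann cells, skeletal muscle, and lung and other neighbouring tissue. Each list was tested with camera at a preset correlation of 0.01, adjusted over the 30 lists, with camera at an estimated correlation and fry as alternatives. A list score, the mean of log2(value + 1) over the members measured in both sexes, was compared within each sex by exact permutation of the mice. The difference between the sexes was also compared by permutation, which is not an exact test of the interaction. Of the 30 lists, 28 had a score.

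An exon bin was counted as changed at the authors' adjusted p under 0.05. For its values, bin counts were divided by the size factors of the gene tables, and the share of a bin is its count relative to the gene's value, on the log2 scale. This share gives the direction of a bin but is not the quantity that the authors tested. A bin can exceed its gene's value, as bin 6 of Myh7 did in wildtype females (12231.5 against 6711). A direction can also rest on a small change, as for bin 15 of Myh7 in males (0.01, with overlapping mice).

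The tests were tested on simulated data with changes placed in 200 genes with at least 100 reads per mouse, at the depth of these libraries and the spread between the wildtype mice, with 5 mice per group. A change of 1.5-fold was recovered for 91.0% of genes in females and 88.5% in males, and 2-fold changes for 100% in both. For the difference between the sexes the shares were 56.5% at 1.5-fold and 98.0% at 2-fold. These shares hold for the spread of wildtype mice, and 200 changed genes make the adjusted threshold easier to pass. In the data Fbp2, with a difference of -2.20 on the log2 scale, had an adjusted p of 0.084 by limma. The shares therefore do not show that a 2-fold difference between the sexes would have been called. False calls made up 1.67% to 8.68% of calls.

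Sequences of transcripts from an older annotation were used only to compare 1 predicted gene with Gapdh, by BLAST 2.17.0. Its coordinates belong to another build and were not used here. Scripts ran under Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Sex differences within wildtype or within knockout mice were not tested, because the tables were scaled separately.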

Results

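Gene expression was measured by RNA sequencing in the left ventricles of 10-week-old mice lacking Rbm20, which encodes a splicing regulator of heart and skeletal muscle, and of wildtype mice, in both sexes. Loss or mutation of RBM20 is a known cause of dilated cardiomyopathy, and the series asks how the sexes differ in it. There were 4 groups of 5 mice, knockout and wildtype females and knockout and wildtype males, with 2 libraries per mouse. Mice are named as in the labels, by ko or wt, sex and number, and ko_f_154 had 1 library that could be matched. Reads in genes per library ranged from 6166106 to 11624594 in knockout females and from 7817093 to 11125655 in wildtype females. In males they ranged from 2351987 to 16973229 in knockouts, both from ko_m_127, and from 5710301 to 10167290 in wildtype. Mitochondrially encoded genes took 26.96 ± 3.23% of the reads in knockout females, 30.99 ± 2.51% in wildtype females, 31.1 ± 3.12% in knockout males and 32.2 ± 3.16% in wildtype males. Expression is given as normalized counts, mean ± SD over mice. Log2 changes, with their SE after ±, and the folds made from them are fitted by limma. Throughout, n = 5 mice per group, and positions are on GRCm39. As a check of the sex labels, Xist had 1239 ± 158 and 1256 ± 231 in knockout and wildtype females against 2.86 ± 2.33 and 3.70 ± 1.72 in males. The Y-linked Ddx3y had 637 ± 61.1 and 544 ± 36.5 in knockout and wildtype males against 0.186 ± 0.257 and 0.126 ± 0.281 in females.

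Rbm20 itself (ENSMUSG00000043639.16, chromosome 19, 53665737 to 53855511) fell in both sexes. In females it went from 1140 ± 125.2 to 404 ± 99.3, a log2 change of -1.52 ± 0.14 (adjusted p = 4.7e-05), and in males from 842 ± 40.3 to 272 ± 35.3, a log2 change of -1.63 ± 0.09 (adjusted p = 9.3e-08). Every knockout mouse was below every wildtype mouse of its sex. Exon bins 6 and 7 of Rbm20 had 0 reads in every knockout mouse, while wildtype females had 16.7 ± 4.35 and 13.3 ± 3.18 and wildtype males 8.08 ± 2.14 and 8.48 ± 2.47. Other bins kept reads in the knockouts, such as bin 18, which had 96.1 ± 27.3 in knockout females and 235 ± 28.6 in wildtype.

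**Figure D1:**
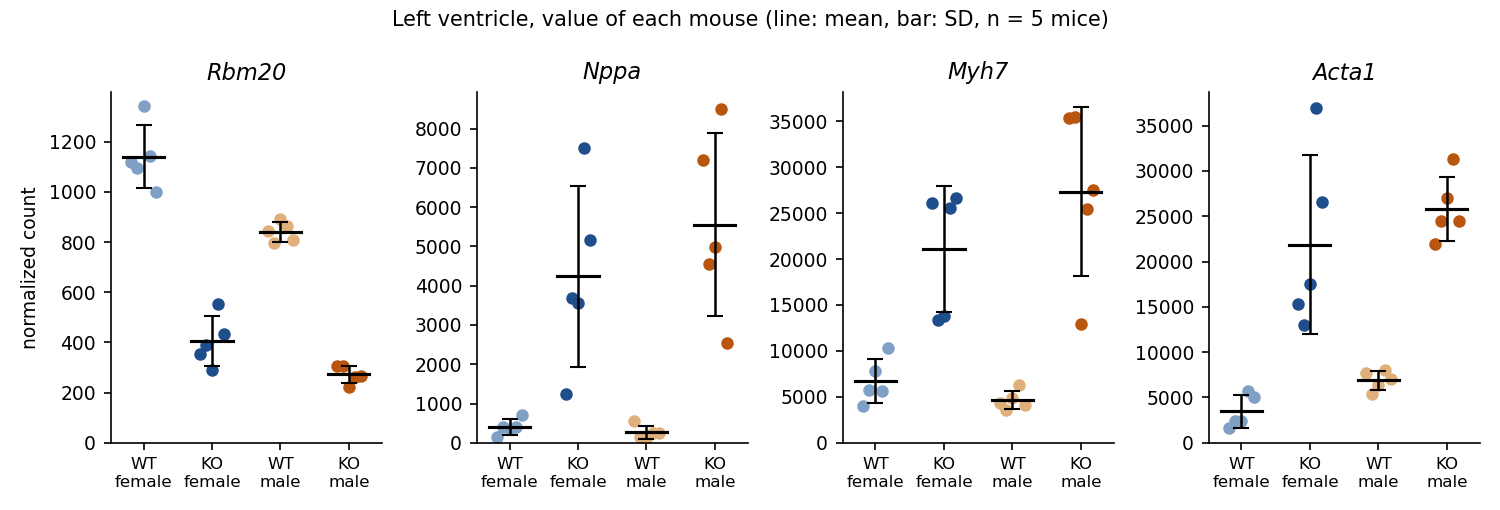
Normalized counts (vertical axis, from 0) of Rbm20, Nppa, Myh7 and Acta1 in the left ventricle of each mouse (points) by group, WT for wildtype and KO for knockout, with the mean (line) and SD (bar) of 5 mice. For all 4 genes the knockout mice of a sex lie on 1 side of the wildtype mice of that sex, with Rbm20 lower and the others higher.

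The first comparison asked which genes differ between knockout and wildtype females. Nppa (ENSMUSG00000041616.10, chromosome 4, 148085179 to 148086536), which encodes atrial natriuretic peptide and is a marker of ventricular stress, rose 10.0-fold, from 402 ± 193 to 4236 ± 2315 (log2 3.32 ± 0.44, adjusted p = 0.00052). Acta1 (ENSMUSG00000031972.6, chromosome 8, 124618508 to 124621490), the skeletal muscle alpha-actin that the fetal heart also makes, rose 6.57-fold from 3456 ± 1827 to 21860 ± 9872. Rtn4r, a receptor for myelin inhibitors of axon growth, fell to 19.5 ± 3.21 in knockouts (log2 -2.23 ± 0.19). Scn4b, a beta subunit of sodium channels, fell from 352 ± 81.4 to 111.8 ± 64.4 (log2 -1.85 ± 0.36). Of 12781 genes tested, 675 rose and 704 fell at an adjusted p under 0.05.

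Among genes with a mean of at least 50, the 10 largest rises in females included Mybpc2, the fast skeletal myosin-binding protein C. It rose 4.97-fold (log2 2.31 ± 0.20), Casq1, the skeletal calsequestrin, rose 3.66-fold (1.87 ± 0.17) and Myot, a Z-disc protein, 3.17-fold (1.67 ± 0.14). Dusp26, a phosphatase, rose 7.37-fold (2.88 ± 0.38) and Fgf6, a fibroblast growth factor, 6.14-fold (2.62 ± 0.38). Nova1, a splicing regulator best known from neurons, rose 4.06-fold (2.02 ± 0.25), Art4 3.75-fold (1.91 ± 0.18) and Gnao1, a G protein alpha subunit, 3.18-fold (1.67 ± 0.12). The 10 largest falls also held Cenpf, a kinetochore protein (log2 -1.77 ± 0.17), and Cep128 (-1.58 ± 0.12). Others among them were Slc9a2, a sodium-proton exchanger (-1.57 ± 0.22), Arhgap9 (-1.45 ± 0.11), Lrrc4b (-1.40 ± 0.17), Sun3 (-1.40 ± 0.18) and Tmod4, a tropomodulin of skeletal muscle (-1.38 ± 0.28). In each of these genes every knockout female lay on 1 side of every wildtype female.

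Genes that the fetal heart expresses or that respond to stress rose as a group in females by camera at the preset correlation. Of the 19 measured members of that list, 10 rose and 9 did not pass, and 11 rose and 1 fell when adjusted over the list alone. Besides Nppa and Acta1, Ankrd1, a titin-binding stress protein, rose 2.53-fold from 20718 ± 2702 to 52555 ± 7357 and Fhl1, a LIM protein of the sarcomere, 2.60-fold. The list's adjusted p was 8.9e-07 by camera, and adjusted p = 0.39 with an estimated correlation. Atrial markers differed between single mice of either genotype. Myl7, an atrial myosin light chain chosen after its values were seen, had 8051 in ko_f_151, 1223 in ko_f_154, 173 in ko_f_150 and 1416 in wt_f_144. It was under 10 in ko_f_95 and ko_f_155, whose mean Nppa was 6347. The atrial list had 1 of 9 members up, Nppa (adjusted over the list alone also 1; camera adjusted p = 0.16).

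Of the sarcomere and Z-disc genes 7 of 33 rose in females and 26 did not pass the threshold (8 up adjusted over the list alone; camera adjusted p = 0.0018, adjusted p = 0.51 with an estimated correlation). Myh7, the slow beta-myosin heavy chain, rose 3.15-fold from 6711 ± 2413 to 21076 ± 6884, Synpo2l 2.78-fold (log2 1.47 ± 0.18), Nrap 1.63-fold (0.70 ± 0.11) and Lmod2, a leiomodin that lengthens thin filaments, 1.41-fold (0.49 ± 0.09). The fast isoform Myh6, chosen after its values were seen, had 187765 ± 30301 in wildtype and 171383 ± 19550 in knockout females and did not pass (adjusted p = 0.67). Of the ion channel and conduction genes 8 of 27 fell and 1 rose (8 and 2 adjusted over the list alone; camera adjusted p = 0.025, adjusted p = 0.51 with an estimated correlation). The pacemaker channel Hcn2 fell from 214 ± 16.4 to 87.6 ± 13.8 (log2 -1.29 ± 0.11). Kcnip2, a partner of potassium channels, fell by 0.49 ± 0.07 on the log2 scale, and Kcnj11, of the ATP-sensitive potassium channel, fell by 0.40 ± 0.07. In calcium handling, Casq1 rose, and Itpr2 (log2 -0.49 ± 0.08) and Hrc (-0.39 ± 0.09) fell, among 22 measured. That list had 1 up and 4 down adjusted over the list alone and camera adjusted p = 0.39. Its median of -0.05 and its downward test stood against a mean of 0.15. Hrc missed the threshold without ko_f_154 (adjusted p = 0.052), wt_f_141 (0.059) or wt_f_142 (0.053).

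In oxidative phosphorylation 8 of 34 genes fell in females and 26 did not pass (16 fell adjusted over the list alone; camera adjusted p = 3.6e-08, adjusted p = 0.50 with an estimated correlation). Sdha (log2 -0.33 ± 0.07) was among them. In glycolysis and glucose use 11 of 26 fell and 15 did not pass (14 adjusted over the list alone; camera adjusted p = 9.4e-07, adjusted p = 0.39 with an estimated correlation). The falls included the phosphofructokinase Pfkl (-0.42 ± 0.08), the lactate dehydrogenase subunit Ldha (-0.24 ± 0.06) and Pdha1 (-0.35 ± 0.08). In fatty acid oxidation 9 of 34 fell and 25 did not pass (14 adjusted over the list alone; camera adjusted p = 2.0e-06, adjusted p = 0.49 with an estimated correlation). Etfa (-0.41 ± 0.08), Cpt2, which imports fatty acids into mitochondria (-0.40 ± 0.08), and Acads (-0.52 ± 0.10) fell. Of the adipocyte markers 4 of 8 rose and 4 did not pass (7 rose adjusted over the list alone; camera adjusted p = 0.00066, adjusted p = 0.44 with an estimated correlation). The fat cell hormone Adipoq, chosen after its values were seen, had 108 ± 130 in knockout and 21.9 ± 19.6 in wildtype females, with 338 in ko_f_151. Cidea (log2 0.32 ± 0.08) kept its call whichever mouse was left out. Cidec did not pass without ko_f_151 (adjusted p = 0.055), ko_f_95 (0.078), wt_f_140 (0.088), wt_f_141 (0.075) or wt_f_143 (0.085). Cfd, at 984 in ko_f_151, passed without ko_f_155, wt_f_142 or wt_f_144 but had an adjusted p of 0.051 to 0.115 without any of the other 7 mice.

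Of the extracellular matrix and fibrosis genes 16 of 39 were higher in females and 23 did not pass (25 higher adjusted over the list alone; camera adjusted p = 2.2e-11, adjusted p = 0.44 with an estimated correlation). Tgfb2, a growth factor, rose 2.54-fold from 160 ± 32.3 to 414 ± 109, Cilp, a matrix protein of activated fibroblasts, 6.05-fold (log2 2.60 ± 0.50), Col8a1 1.78-fold (0.83 ± 0.15) and Col1a2 1.52-fold (0.61 ± 0.11). Of the fibroblast markers 5 of 16 rose and 11 did not pass (6 up and 1 down adjusted over the list alone; camera adjusted p = 0.0013, adjusted p = 0.44 with an estimated correlation). They included Dcn (log2 0.53 ± 0.11), Col1a1 (0.72 ± 0.15) and Abca8a (0.26 ± 0.06), and Dcn and Col1a1 are in the matrix list too. Of the endothelial markers 3 of 20 fell and 17 did not pass (2 up and 6 down adjusted over the list alone; camera adjusted p = 0.039, adjusted p = 0.56 with an estimated correlation). Cdh5, VE-cadherin (-0.43 ± 0.08), and the growth factor receptor Kdr (-0.50 ± 0.10) fell.

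Of the immediate early genes 4 of 18 rose and 14 did not pass (5 adjusted over the list alone; camera adjusted p = 0.0014, adjusted p = 0.50 with an estimated correlation). Myc, a growth regulator, rose by 0.59 ± 0.14 on the log2 scale. In the integrated stress response 3 of 17 rose (5 up and 1 down adjusted over the list alone; camera adjusted p = 0.029, adjusted p = 0.51 with an estimated correlation). They included Chac1 (1.54 ± 0.33) and the amino acid transporter subunit Slc3a2 (0.38 ± 0.07). Of the splicing factors 4 of 20 fell and 2 rose (4 and 3 adjusted over the list alone; camera adjusted p = 0.87), with the deleted Rbm20 among the falls. Rbfox1, a splicing regulator of muscle and neurons, fell from 472 ± 102 to 204 ± 22.7 (-1.18 ± 0.14) and Celf1 by 0.28 ± 0.05. In the RBM20 splicing targets, tested at the level of whole genes, 3 rose and 3 fell of 34 (3 and 3 adjusted over the list alone; camera adjusted p = 0.87), with Enah (0.68 ± 0.12) and Rtn4 (0.65 ± 0.07) up and Sh3kbp1 (-0.35 ± 0.08) down.

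Other lists had single members that passed but no call as a list in females. Heat shock genes had 2 up and 1 down of 20 (3 and 1 adjusted over the list alone; camera adjusted p = 0.061), with Hspb7, a small heat shock protein of muscle, up by 0.58 ± 0.09. The circadian clock had 2 up of 18 (5 adjusted over the list alone; 0.061), with Bhlhe40 at 0.38 ± 0.09, which missed the threshold without wt_f_141 (adjusted p = 0.052). The other, Bhlhe41 (0.55 ± 0.16), had an adjusted p of 0.055 to 0.102 without ko_f_150, ko_f_154, ko_f_155, ko_f_95, wt_f_140, wt_f_143 or wt_f_144. Without 1 mouse 1 to 4 clock genes passed, with 4 without wt_f_142. Inflammation and interferon genes had 2 up of 19 (2 adjusted over the list alone; 0.39), with Lcn2 at 0.80 ± 0.20. Lcn2 missed the threshold without ko_f_95 (adjusted p = 0.052), wt_f_140 (0.055) or wt_f_141 (0.053). Nfkbia (0.44 ± 0.13) kept its call without ko_f_150 and had an adjusted p of 0.054 to 0.105 without any of the other 9 females, so both calls were lost without ko_f_95, wt_f_140 or wt_f_141. The cell cycle had 2 up of 14 (3 adjusted over the list alone; 0.993), with the cyclin Ccnd2 at 0.90 ± 0.09. Skeletal muscle genes had 1 up and 2 down of 4 on either count (0.87), with the creatine kinase Ckm at -0.38 ± 0.07. Mural cells had 1 up and 1 down of 11 on either count (0.9965), with Abcc9 at -0.54 ± 0.11, and lung had Tg down of 2 on either count (0.35). In 7 lists no member passed in limma. Among them, mitochondrially encoded genes had camera adjusted p = 0.025, adjusted p = 0.49 with an estimated correlation and a median log2 change of -0.31 over 13. The others were macrophage and myeloid (camera adjusted p = 0.51, 17 members), lymphocyte (0.70, 3), red blood cell (0.42, 6), neural and Schwann cell (0.87, 6), sex hormone receptors (0.993, 6) and sex-linked genes (0.993, 5). Of the 56 members of these lists 7 had an unadjusted p under 0.05, 1 passed in edgeR and 3 in DESeq2. Adjusted over the list alone, the sex hormone list had 1 up and 2 down and the other 6 had none by limma. Test, median and mean differed in sign for mural cells (test down, median -0.09, mean 0.08), skeletal muscle (down, 0.02, 0.57) and the cell cycle (up, -0.16, -0.08). Without the 3 females whose Myl7 was at least 500, an alternative chosen after seeing the data, 1220 genes passed. Counting each library as a replicate would give 3322 genes, since the libraries of 1 mouse are not independent.

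Leaving out 1 female moved many of these counts by more than 1.5 times. The 8 falls in oxidative phosphorylation became 2 without ko_f_151, ko_f_95, wt_f_140 or wt_f_141, 3 without wt_f_143, 4 without ko_f_150, ko_f_154 or wt_f_142, and 17 without wt_f_144. The 11 falls in glycolysis became 5 or 6 without ko_f_154, ko_f_95, wt_f_140, wt_f_141, wt_f_142 or wt_f_143. The 16 rises in the matrix list became 9 or 10 without ko_f_154, wt_f_140, wt_f_141 or wt_f_142. The 4 adipocyte rises became 1 without ko_f_95, wt_f_140, wt_f_141 or wt_f_143 and 2 without ko_f_151. The 4 rises of immediate early genes became 1 without ko_f_154 or wt_f_141 and 2 without wt_f_140. The 2 heat shock rises became 1 without ko_f_151, ko_f_155, ko_f_95, wt_f_140, wt_f_141 or wt_f_142, and the heat shock fall was kept without wt_f_140 or wt_f_142 alone. The 2 rises in the cell cycle became 1 without ko_f_150, ko_f_154, ko_f_95, wt_f_140, wt_f_141 or wt_f_142. The 2 falls in calcium handling became 1 without ko_f_154, wt_f_141 or wt_f_142, and the mural rise was lost without ko_f_154, ko_f_155, ko_f_95, wt_f_140, wt_f_141 or wt_f_142. Without wt_f_144 there were 26 rises in the matrix, 7 in adipocyte markers, 5 in the integrated stress response, 4 in heat shock genes and 2 in mural cells. Falls without wt_f_144 were 14 in fatty acid oxidation, 7 in the splicing targets and 5 in calcium handling. The 3 rises in the integrated stress response became 6 without ko_f_150. Other counts of 0 or 1 moved by at most 1, except that 2 atrial markers fell without ko_f_151.

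The second comparison asked the same of males. Nppa rose 22.6-fold, from 265 ± 174 to 5558 ± 2338 (log2 4.50 ± 0.37, adjusted p = 2.7e-06), while the atrial Myl7, chosen after its values were seen, was 0.769 ± 0.521 in knockout males. Myh7 (ENSMUSG00000053093.17, chromosome 14, 55208141 to 55232083) rose 5.65-fold from 4643 ± 1010 to 27322 ± 9209. Fbp2 (ENSMUSG00000021456.9, chromosome 13, 62984691 to 63006236), the muscle form of the gluconeogenic enzyme fructose-bisphosphatase, fell from 158.7 ± 15.5 to 18.9 ± 11.3 (log2 -3.19 ± 0.29, adjusted p = 6.4e-06). Most genes of fatty acid oxidation fell, 27 of 34, with a median log2 change of -0.52. Of 12506 genes tested, 950 rose and 1037 fell.

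Among genes with a mean of at least 50, the 10 largest rises in males also held Tbx15, a transcription factor (log2 2.95 ± 0.33), Edn3, an endothelin (2.91 ± 0.23), and Fgf6, up 6.50-fold. They were completed by Nmrk2, a kinase of NAD synthesis in muscle (2.09 ± 0.21), Mybpc2 (2.07 ± 0.13), Synpo2l (1.97 ± 0.17), Acta1 (1.91 ± 0.13) and Nppb, B-type natriuretic peptide (1.85 ± 0.16). Nppb went from 1846 ± 379 to 6697 ± 1632. The 10 largest falls also held Nrgn (log2 -2.17 ± 0.41), the kinase Mylk4 (-1.81 ± 0.20), and Fah, of tyrosine breakdown (-1.74 ± 0.11). Others among them were Scn4b (-1.72 ± 0.35), Cep128 (-1.67 ± 0.10), Pfkfb1, which makes and breaks down a regulator of glycolysis (-1.67 ± 0.23), Pdk4, the kinase that shuts off pyruvate dehydrogenase (-1.61 ± 0.36), and Mhrt (-1.58 ± 0.15). Mhrt is an RNA antisense to Myh7 and overlaps it, and the strand of the libraries is not stated, so reads of the pair cannot be assigned with confidence.

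In fatty acid oxidation the 27 falls left 7 members not past, and 28 fell when adjusted over the list alone (camera adjusted p = 6.3e-17, adjusted p = 0.32 with an estimated correlation). Acot1, a thioesterase, fell from 45.7 ± 7.02 to 11.6 ± 4.53 (log2 -1.94 ± 0.22). Cpt2 fell from 1728 ± 169 to 1018 ± 175 (-0.77 ± 0.11), and Acot2 fell by 0.82 ± 0.12. In oxidative phosphorylation 9 of 34 fell and 25 did not pass (21 adjusted over the list alone; camera adjusted p = 1.7e-08, adjusted p = 0.45 with an estimated correlation). Cox7a1 was at -0.65 ± 0.14 and Uqcrc1 at -0.47 ± 0.10. In glycolysis and glucose use 8 fell and 1 rose of 26 (10 and 1 adjusted over the list alone; camera adjusted p = 0.00023, adjusted p = 0.40 with an estimated correlation). Pfkfb1, Gys1, glycogen synthase (-0.46 ± 0.08), and Pdk2 (-0.39 ± 0.09) fell. Of 4 adipocyte markers, Fabp4 fell (-0.51 ± 0.12) and 3 did not pass (1 down adjusted over the list alone; camera adjusted p = 0.50), and Adipoq had 10.5 ± 9.77 in knockout and 5.74 ± 2.12 in wildtype males.

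**Figure D2:**
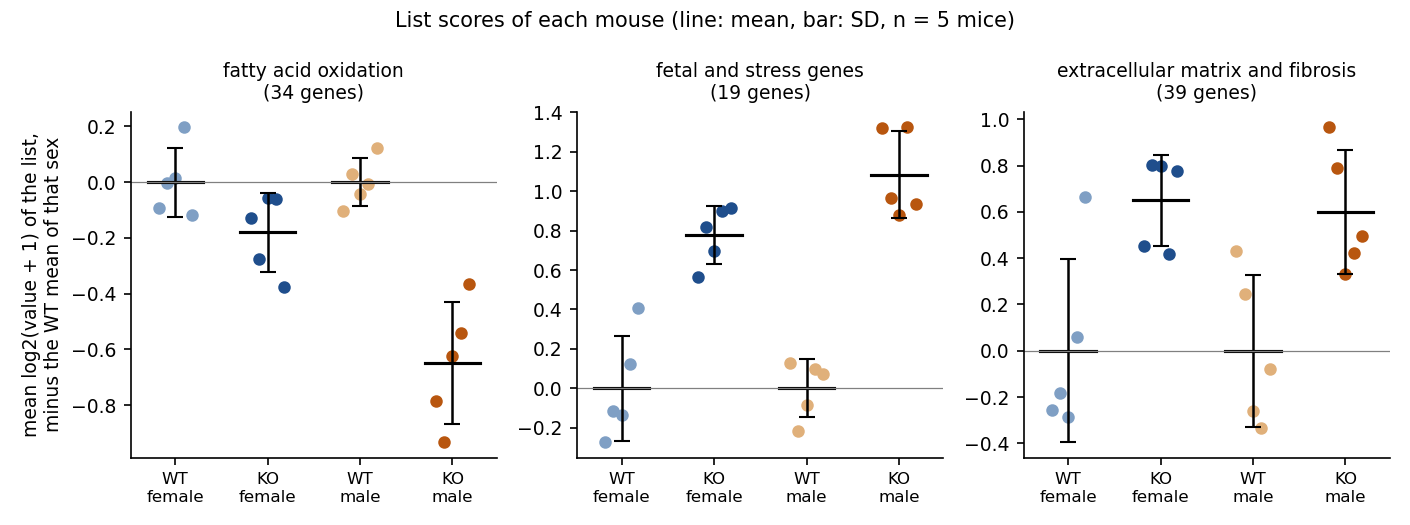
Score of 3 gene lists in each mouse (points), the mean of log2(value + 1) over the list's genes minus the wildtype mean of that sex (vertical axis), by group, with the mean (line) and SD (bar) of 5 mice. The fatty acid oxidation score lies between -0.93 and -0.37 in knockout males and between -0.38 and -0.06 in knockout females, and the fetal and stress score and the matrix score are above 0, the wildtype mean, in all 10 knockout mice. For the matrix score the genotypes overlap. Wildtype mice reach 0.66 in females and 0.43 in males, and the lowest knockouts are at 0.42 and 0.33.

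Of the fetal and stress genes 12 of 19 rose, 1 fell and 6 did not pass in males (13 and 1 adjusted over the list alone; camera adjusted p = 2.1e-10, adjusted p = 0.15 with an estimated correlation). Ankrd1 rose 2.95-fold from 22181 ± 2096 to 66148 ± 12262. Of the sarcomere and Z-disc genes 10 of 33 rose and 23 did not pass (10 adjusted over the list alone; camera adjusted p = 0.00067, adjusted p = 0.40 with an estimated correlation). They included Nrap (log2 1.07 ± 0.13) and Lmod2 (0.63 ± 0.12). Myh6 had 131918 ± 16171 in wildtype and 97852 ± 17079 in knockout males and did not pass (adjusted p = 0.10). Of the ion channel genes 12 of 25 fell and 13 did not pass (14 adjusted over the list alone; camera adjusted p = 3.8e-07, adjusted p = 0.15 with an estimated correlation). Hcn2 went from 193 ± 24.5 to 70.0 ± 15.8 (-1.47 ± 0.15), and the pacemaker channel Hcn4 went to 38.7 ± 12.3 (-1.40 ± 0.18). Kcnj3, which is in the atrial list too, had a log2 change of -0.93 ± 0.10 and the delayed rectifier Kcnh2 of -0.81 ± 0.10. Calcium handling had 5 up and 3 down of 22 on either count (camera adjusted p = 0.89). Casq1 rose by 1.25 ± 0.12, and Atp2a2, the calcium pump of the sarcoplasmic reticulum, fell from 56194 ± 2258 to 38262 ± 2819 (-0.56 ± 0.11). Of 9 atrial markers 4 fell and Nppa rose (5 and 1 adjusted over the list alone; camera adjusted p = 0.051), the falls including Stard10 (-0.62 ± 0.12), Tbx5 (-0.44 ± 0.09) and Myl7 (-4.49 ± 1.18). Myl7 was 692 in wt_m_112 and 130.1 in wt_m_113.

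In the extracellular matrix list 22 of 39 rose in males and 17 did not pass (25 adjusted over the list alone; camera adjusted p = 4.7e-12, adjusted p = 0.40 with an estimated correlation). They included Tgfb2, up 3.35-fold (log2 1.74 ± 0.20), Col15a1 1.88-fold (0.91 ± 0.13), Loxl2 1.76-fold (0.81 ± 0.09) and Lum 1.67-fold (0.74 ± 0.11). Alongside them 6 of 16 fibroblast markers rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.00072, adjusted p = 0.40 with an estimated correlation). They included Pdgfra (0.57 ± 0.11) and Medag (0.56 ± 0.10). Endothelial markers had 4 of 20 down and 1 up (6 and 1 adjusted over the list alone; camera adjusted p = 0.00057, adjusted p = 0.40 with an estimated correlation). They included Car4 (-0.57 ± 0.11) and Esam (-0.34 ± 0.07). Red blood cell markers had 3 of 6 down (5 adjusted over the list alone; camera adjusted p = 0.0014, adjusted p = 0.40 with an estimated correlation). They included the globin Hbb-bt (-0.84 ± 0.20). The platelet gene Ppbp, chosen after its values were seen, went from 158.5 ± 135.2 to 22.8 ± 6.18 in males (log2 -2.33 ± 0.48, adjusted p = 0.0037, at most 0.012 whichever mouse was left out). The highest male was wt_m_139 for Ppbp (385), for Nrgn (295) and for the globin Hba-a1 (21199). Immediate early genes had 9 of 18 up on either count (camera adjusted p = 0.00057, adjusted p = 0.40 with an estimated correlation). They included Egr3 (1.85 ± 0.22) and Egr2 (1.73 ± 0.31). The integrated stress response had 3 up and 1 down of 17 (7 and 1 adjusted over the list alone; camera adjusted p = 0.039, adjusted p = 0.40 with an estimated correlation), including Gdf15, a secreted stress signal (1.39 ± 0.24). Sex-linked genes had 3 up of 8 (5 adjusted over the list alone; camera adjusted p = 0.0053, adjusted p = 0.40 with an estimated correlation). The Y-linked Kdm5d (0.36 ± 0.10) kept its call whichever mouse was left out. Kdm6a (0.25 ± 0.08) had an adjusted p of 0.054 to 0.085 without any mouse but ko_m_97, and Eif2s3x (0.26 ± 0.08) of 0.057 to 0.096 without ko_m_106, ko_m_127, ko_m_128, ko_m_97, wt_m_112, wt_m_124 or wt_m_139. Without ko_m_106, ko_m_127, ko_m_128, wt_m_112, wt_m_124 or wt_m_139 this left 1 of the 3.

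Splicing factors had 3 up and 3 down of 20 in males (4 and 6 adjusted over the list alone; camera adjusted p = 0.88). Rbfox1 was at -1.19 ± 0.10, Celf2 at 0.51 ± 0.08 and Nova1 at 1.32 ± 0.26. RBM20 splicing targets had 6 up and 2 down of 34 (8 and 3 adjusted over the list alone; camera adjusted p = 0.46), with Enah at 1.03 ± 0.16 and Kcnip2 at -0.59 ± 0.10. The other lists gave no call as lists. Heat shock genes had 3 up and 1 down of 19 (4 and 1 adjusted over the list alone; camera adjusted p = 0.51), with Hspb7 at 0.71 ± 0.13. The clock had 2 up of 16 on either count (0.59), with Bhlhe40 at 0.79 ± 0.12, and the cell cycle 1 up of 14 on either count (0.40), Ccnd2 at 0.89 ± 0.12. Sex hormone receptors had 1 up and 1 down of 6 (1 and 2 adjusted over the list alone; 0.68), with Hsd17b4 at -0.42 ± 0.07. Mural cells had 1 up and 1 down of 11 on either count (0.71), with Des at 0.56 ± 0.12. Macrophage and myeloid markers had Cx3cr1 up of 17 on either count (1.06 ± 0.29; camera adjusted p = 0.93), a call lost without ko_m_127 (adjusted p = 0.055), ko_m_128 (0.051) or wt_m_139 (0.052). Neural and Schwann cell markers had Dbh, of noradrenaline synthesis, down of 6 on either count (-1.71 ± 0.19; 0.11), and skeletal muscle genes had Acta1 up and Ckm down of 4 (1 and 2 adjusted over the list alone; 0.59). Lung had Tg down as its 1 measured gene (-1.15 ± 0.27; 0.14), and inflammation had Ifi44 down of 18 (-0.77 ± 0.24; 0.62), which did not pass when adjusted over the list alone. Ckm missed the threshold without ko_m_106 (adjusted p = 0.060), ko_m_127 (0.068), wt_m_124 (0.06996) or wt_m_125 (0.0695). Ifi44 kept it without ko_m_128, wt_m_125 or wt_m_139 and had an adjusted p of 0.055 to 0.110 without any of the other 7 mice. In the mitochondrially encoded (camera adjusted p = 0.71, 13 members) and lymphocyte lists (0.885, 2) no member passed in limma, edgeR or DESeq2 or had an unadjusted p under 0.05. Test, median and mean differed in sign for macrophages (test down, median -0.04, mean 0.03), skeletal muscle (up, -0.05, 0.36), heat shock (up, -0.00018, 0.08), the clock (up, -0.01, 0.10), sex hormone receptors (down, 0.05, -0.11) and splicing factors (down, 0.03, -0.03). Without wt_m_112, whose Myl7 was at least 500, 1766 genes passed. With Myl7 as a covariate 965 passed, both alternatives being chosen after seeing the data.

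Leaving out 1 male moved several of these counts by more than 1.5 times. The 9 falls in oxidative phosphorylation became 4 without ko_m_106 or ko_m_127 and 5 without wt_m_113, wt_m_124, wt_m_125 or wt_m_139. The 9 rises of immediate early genes became 5 without ko_m_106, ko_m_128, ko_m_97, wt_m_112 or wt_m_113. The 4 endothelial falls became 2 without ko_m_130, ko_m_97, wt_m_112, wt_m_113, wt_m_124 or wt_m_139 and 7 without ko_m_127, and the 3 red blood cell falls became 5 without ko_m_97. Single calls were lost in the fetal list (the fall, without ko_m_127, ko_m_128, ko_m_130, wt_m_124, wt_m_125 or wt_m_139) and in glycolysis (the rise, without ko_m_106, ko_m_130, wt_m_113, wt_m_124 or wt_m_139). The fibroblast fall was kept without ko_m_97, wt_m_112 or wt_m_125 alone, the endothelial rise without ko_m_128, wt_m_112 or wt_m_139, and the sex hormone rise without ko_m_97 or wt_m_112. The heat shock fall was lost without ko_m_106, wt_m_124 or wt_m_125. Other counts of 0 or 1 moved by at most 1.

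The changes of the sexes overlapped. Of 12462 genes tested in both, 418 rose in both and 436 fell in both, where 49.8 and 57.4 would be expected if the calls were independent, and 1 gene, Trim7, rose in females and fell in males. The shared calls included Rbm20, Nppa, Acta1, Myh7, Mybpc2, Fgf6, Tgfb2, Ankrd1, Hcn2, Scn4b, Cep128 and Rbfox1. Pearson's r between the log2 changes was 0.68 across genes, which are not independent replicates. Females and males had no libraries in common.

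**Figure D3:**
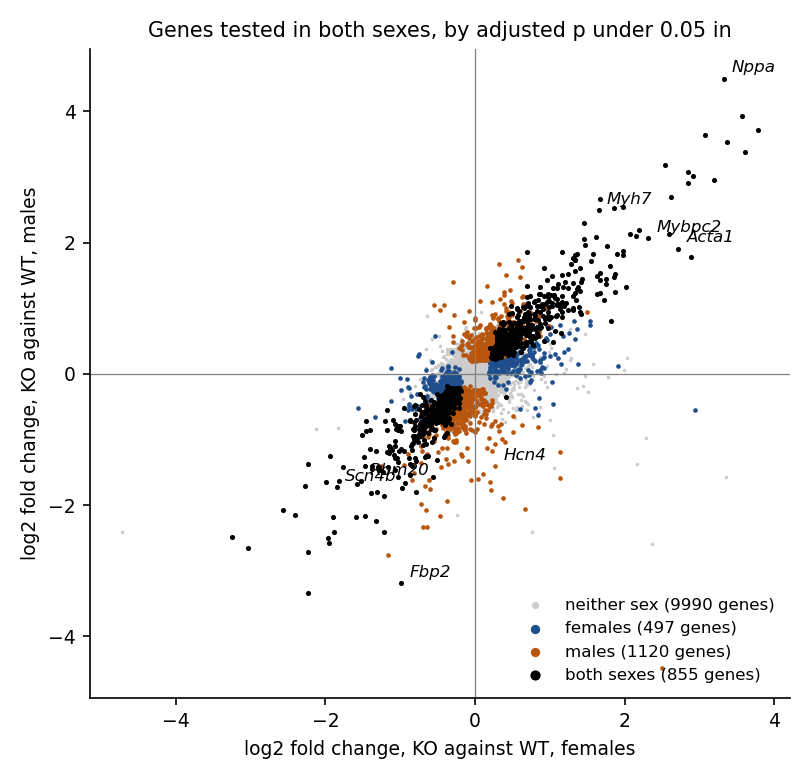
Log2 fold change of each of 12462 genes (points) between knockout and wildtype in females (horizontal axis) and in males (vertical axis), coloured by the sex in which the limma adjusted p was under 0.05. It passed in both sexes for 855 genes, in females alone for 497 and in males alone for 1120, and a call in 1 sex alone is no test of a difference between the sexes.

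Whether the knockout changed genes differently in males and females was tested by the interaction of sex and genotype. Among the fold changes that stood furthest apart by p were those of Aldh9a1, an aldehyde dehydrogenase of carnitine synthesis (log2 0.00075 in females and -0.89 in males), Trim7 (0.42 and -0.35), the pacemaker channel Hcn4 (0.26 and -1.40) and Rem1 (-0.29 and 0.49), each with an adjusted p of 0.078. They were followed by Fbp2 (-0.99 and -3.19), Irf8, a transcription factor of myeloid cells (-0.14 and 0.79), Mhrt (-0.56 and -1.58) and Retsat (-0.06 and -0.75), each with an adjusted p of 0.084. Ckap4 (-0.15 and 0.61) had 0.091. For Fbp2 the male change minus the female change was -2.20 ± 0.44 and for Hcn4 -1.66 ± 0.31. By limma 0 of 12462 genes passed, with 1003 at an unadjusted p under 0.05, while edgeR on the recovered reads called 0 and DESeq2 45, both chosen after seeing the data. These genes had adjusted p-values of 0.073 to 0.117 in edgeR and of 0.00073 to 0.011 in DESeq2. Leaving out ko_f_95 gave 14 genes, ko_m_97 gave 11, wt_f_143 gave 3 and ko_f_154 gave 1.

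As groups, fatty acid oxidation genes were lower in the difference, meaning that their change in males was below that in females. The median of the 34 members was -0.28, 11 were lower when adjusted over the list alone (0 over all genes tested), and camera gave an adjusted p of 4.8e-13, but adjusted p = 0.46 with an estimated correlation. The list score changed by -0.18 in females and by -0.65 in males, with a permutation p of 0.0026 for the difference, or 0.073 adjusted over 28 lists. A permutation p for the difference is exact only if the labels exchanged have no effect of their own. It is therefore no exact test of an unequal knockout effect. In males alone the score's exact permutation p was 0.0079, the smallest that the 252 permutations can give, and in females 0.071. Testing the lists in the difference was chosen after seeing the data. Camera also called adipocyte markers (adjusted p = 0.0011, adjusted p = 0.12 with an estimated correlation). It further called ion channels, atrial, neural and Schwann cell markers and sex-linked genes (each adjusted p = 0.016, adjusted p = 0.66 with an estimated correlation) and fetal and stress genes (adjusted p = 0.031, adjusted p = 0.66 with an estimated correlation). Medians were -1.20 for the 4 adipocyte markers, -0.18 for ion channels, -0.74 for atrial, -0.41 for neural, 0.19 for sex-linked and 0.11 for fetal and stress genes. Adjusted over the list alone, 2 adipocyte, 3 ion channel and 1 neural marker were lower in the difference, and 1 sex-linked and 3 fetal and stress genes higher. Counted the same way, the sarcomere, macrophage and integrated stress response lists had 1 member higher each and inflammation 1 lower. Across the 30 lists 69 of 507 members had an unadjusted p under 0.05, and 0 passed in limma or edgeR and 9 in DESeq2. The other 23 lists had adjusted p-values of 0.075 to 0.93, and test, median and mean differed in sign for calcium handling (test up, median 0.03, mean -0.21), glycolysis (up, 0.01, -0.01), extracellular matrix (up, 0.08, -0.05), mural cells (down, 0.02, -0.10) and splicing factors (up, 0.02, -0.02).

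The exon tables ask which parts of genes are used differently, which a splicing factor can change. Reads of overlapping or nearly identical genes can move a bin too, so a changed bin is not by itself a change of splicing. In knockout females the bins of Ttn (ENSMUSG00000051747.16, chromosome 2, 76534324 to 76812891), which encodes the elastic protein titin, stood out: 99 bins passed the authors' threshold with a higher share in knockouts and 7 with a lower one. The higher ones lay between bins 157 and 329, with bin 221 at 0.379 in wildtype and 112.8 in knockout females, while the lower ones were bins 310, 333, 334, 335, 342, 350 and 353. Ldb3, a Z-disc scaffold, had bin 17 at 33.3 ± 2.38 in wildtype and 551 ± 63.6 in knockout females (log2 share change 3.91). Its bin 18 was at 16.6 ± 2.44 and 259 ± 30.7. At the level of the whole gene Ttn (adjusted p = 0.26) and Ldb3 (adjusted p = 0.50) did not pass in limma.

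Bins of other splicing targets changed in both directions. In females bin 50 of Camk2d, a calcium-dependent kinase, went from 6.71 ± 3.36 to 47.4 ± 10.6, and bin 32 of the calcium release channel Ryr2 from 1.26 ± 0.712 to 12.9 ± 5.15. Bin 29 of Myom1 went from 40.8 ± 15.4 to 184.8 ± 38.2. Bin 19 of Mlip had a share change of 0.79. Camk2d had 2 bins with a higher and 2 with a lower share and Mlip 3 and 5, while the only bins of Pdlim5, Nexn and Cacna1c were lower. In all, 833 bins of 372 genes passed in females, 469 with a higher and 343 with a lower share, and 21 without a gene value. Of the 34 targets 15 had at least 1 such bin. Genes with the most bins included Ttn, Myh7 (29), Gapdh (18), Ano10 (14), Lars (14), Ift81 (10), and Camta1, Emc9, Ldhb, Mlip and Slmap (8 each). In Slmap all 8 were lower and in Camta1 7. These counts follow the authors' test, for which each library is a sample, and Myh7 bins can hold reads of the overlapping Mhrt. Of the female bins with a gene value, 491 (60.5%) had every knockout mouse's share on 1 side of every wildtype mouse.

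**Figure D4:**
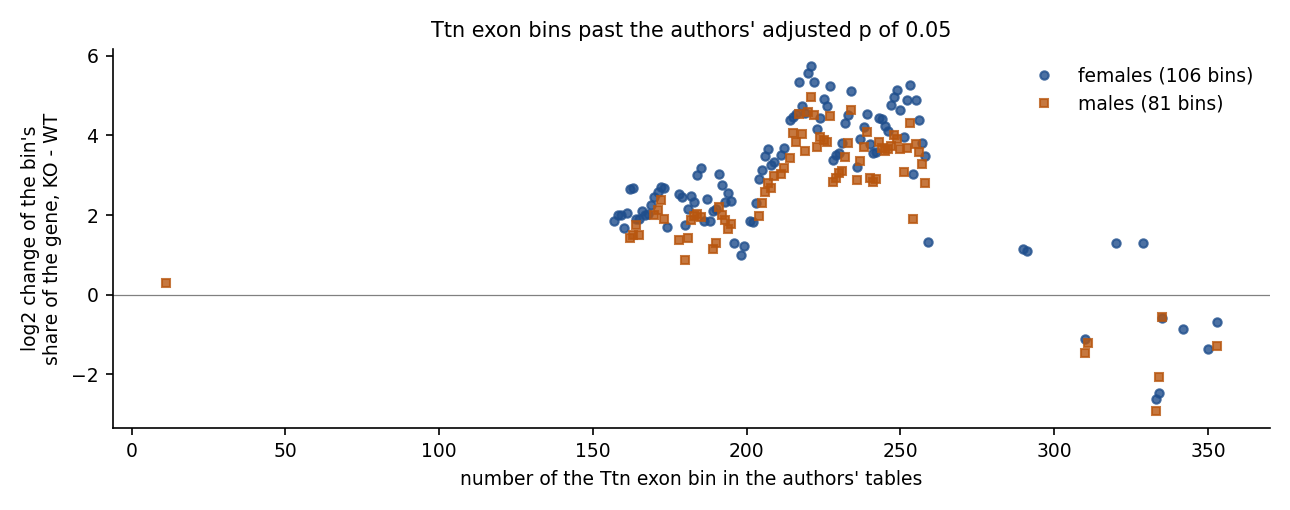
Log2 change of the share of each Ttn exon bin in its gene (vertical axis), knockout minus wildtype, against the bin's number (horizontal axis), for the bins in females (circles) and males (squares) past the authors' adjusted p of 0.05. The largest change is in bin 221 in both sexes, at 5.73 in females and 4.96 in males, and bins 333 and 334 are lower in both.

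In males 81 bins of Ttn passed, 75 with a higher share and 6 with a lower one, with bin 221 listed at 0 in every wildtype male and at 44.4 in knockouts, and bins 310, 311, 333, 334, 335 and 353 lower. Ldb3 bin 17 went from 40.5 ± 9.21 to 537 ± 130 (share change 3.72) and bin 18 from 15.6 ± 4.01 to 257 ± 62.4. Camk2d bin 50 went from 5.48 ± 1.52 to 49.8 ± 4.95 and Ryr2 bin 32 from 0.986 ± 0.325 to 10.3 ± 1.71. Bin 7 of Rtn4 rose from 157 ± 25.4 to 433 ± 148 (share change 0.57). Camk2d had 3 bins higher and 2 lower, Mlip 5 and 3 and Rtn4 1 and 3, and both bins of Fhod3 were lower. Myom1, with 20 listed bins in males, and Cacna1c, with 8, had 0 past the threshold there. Rtn4 and Fhod3 had 0 past it in females. A bin called in 1 sex alone is no test of a difference between the sexes. In all, 2157 bins of 1209 genes passed, 1247 higher and 835 lower, with 75 without a gene value. Of the 34 targets 20 had at least 1, and the targets held 160 bins, or 7.42%. Of the male bins with a gene value, 860 (41.3%) had every knockout mouse's share on 1 side of every wildtype mouse. In both bins of Fhod3 the mice overlapped. Genes with the most bins included Ttn, Myh7 (42), Gapdh (19), Ano10 and Ift81 (16 each), Myl12b (15), Camta1 (14), Entpd5 (12) and Slmap (10). Of 419 bins past the threshold in both sexes, 402 had a gene value and 386 of these changed the same way. A limma test of the share for these 402 bins, chosen after seeing the data, gave 0 whose change differed between the sexes and 33 at an unadjusted p under 0.05, and edgeR and DESeq2 were not run on shares. Bins past the threshold in 1 sex alone were left out of this test, so it cannot find bins that change in 1 sex only.

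Gapdh, a glycolytic enzyme often taken as a reference gene, had bins 33 and 34 far higher in most knockout mice. In females bin 33 was 26.7 ± 4.72 in wildtype and 1595 ± 672 in knockout, and in males 27.5 ± 4.09 and 1173 ± 883. The whole gene did not pass (log2 0.0025 ± 0.10 in females and 0.17 ± 0.13 in males). The predicted gene Gm13394 (ENSMUSG00000083773.5, chromosome 2, 28823622 to 28824621), chosen after its values were seen in males, had 4352 ± 374 in wildtype and 992 ± 907 in knockout females. In males it had 3268 ± 364 and 1618 ± 1307, and it did not pass in either sex (adjusted p = 0.078 and 0.20). Its transcript is 99.9% identical to Gapdh over 1000 bases, so reads of the pair cannot be assigned with confidence. For Gm13394 ko_f_150, ko_f_151 and ko_m_97 had 4.81, 3.73 and 6.34, and for bin 33 they had 2377, 2283 and 2514. In ko_m_130 the values were 3656 and 33.2. The other 6 knockout mice had 1407 to 1806 for Gm13394 and 1062 to 1186 for bin 33. In females bin 6 of Ldhb was at 874 ± 84.1 in wildtype and 1369 ± 63.4 in knockout. Ldhb-ps, named as a pseudogene of Ldhb and chosen after its values were seen, fell from 1584 ± 170 to 700.3 ± 40.4, and whether the pair share reads was not checked.

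**Figure D5:**
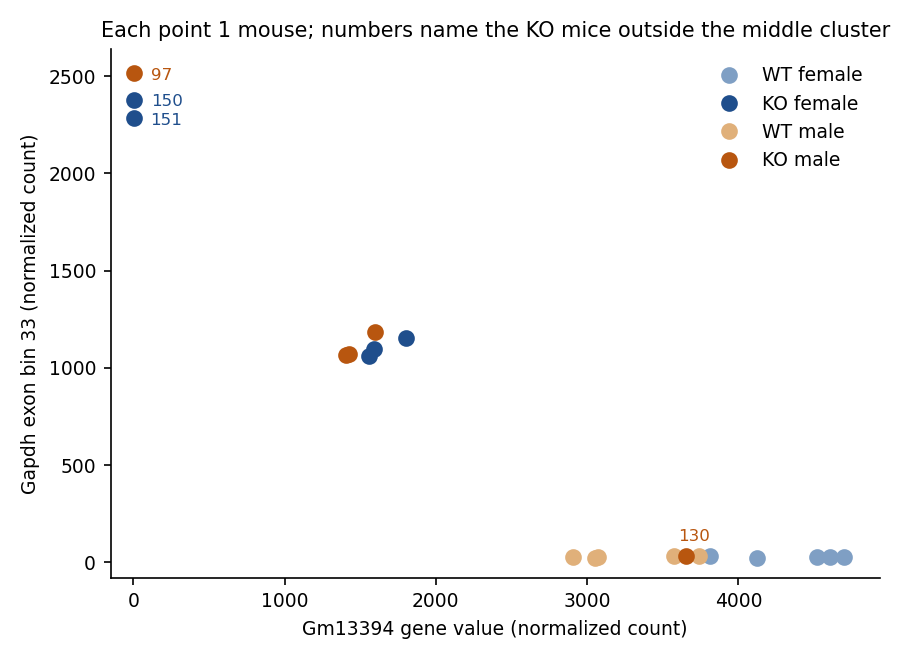
Normalized count of Gapdh exon bin 33 (vertical axis) against that of the predicted gene Gm13394 (horizontal axis) in each of 20 mice (points), WT for wildtype and KO for knockout. All 10 wildtype mice and ko_m_130 have Gm13394 of at least 2909 and a bin of at most 33.6, while ko_m_97, ko_f_150 and ko_f_151 have Gm13394 of at most 6.34 and a bin of at least 2283 and the other 6 knockout mice lie between.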

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

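The tests of the lists in the difference between the sexes, of atrial tissue, of linkage to Rbm20 by odds ratio and of a knockout effect on Gapdh splicing were chosen only after the results were seen, and the Gapdh pattern and the gene Gm13394 were found in the data before they were tested. Of 100 splits of the 10 females into groups of 5, the real one alone gave as many genes, 1 of 100, with 1379 against at most 293 in the others. In males it was again 1 of 100, with 1987 against at most 2, so chance is an unlikely source of both counts. With 100 splits, 1 of 100 is the lowest possible result. The splits cannot tell the knockout from anything else that the knockout mice share. For the difference between the sexes, the sex labels were exchanged within genotype. Counting the real labels, 19 of 100 labellings gave as many genes at an unadjusted p under 0.05, with 1003 for the real labels and up to 1840 for others. Chance is therefore not excluded there.

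Among the groups of genes named, 7 had 1 mouse that stood apart from the other 4 by Dixon's test. Chance marks about 1 in 20 groups, or 6.4 of those tested, so this total is what chance gives. Apart from Casq1, the genes concerned are all among those named for the smallest p of the difference between the sexes. Casq1 was 3869 in ko_m_130 and 2788 to 3055 in the other knockout males. Mhrt was 238 in ko_f_155 and 163.5 to 179 in the other knockout females. Hcn4 was 95.4 in wt_f_141 and 69.6 to 75.5 in the other wildtype females. Aldh9a1 was 277 in wt_m_124 and 235 to 246 in the other wildtype males. Trim7 was 209 in wt_f_143 and 147.9 to 161 in the other wildtype females. Rem1 was 99.1 in wt_m_124 and 75.4 to 77.6 in the other wildtype males. Irf8 was 83.5 in wt_f_140 and 69.9 to 72.9 in the other wildtype females.

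Besides fatty acid oxidation, the knockout change of 6 lists differed between the sexes by camera at the preset correlation, and with an estimated one their adjusted p was 0.12 for adipocyte markers and 0.66 for the others. The adjusted p was 0.001145 for adipocyte markers and 0.01612 for ion channels, for atrial markers and for neural and Schwann cell markers, whose change in males lay below that in females. It was 0.01612 for sex-linked genes and 0.03056 for fetal and stress genes, whose change in males lay above that in females. The atrial list shares Nppa with the fetal list, Kcnj3 and Tbx5 with the ion channels and Sln with calcium handling. Myl7 reached 8051 in ko_f_151, 1416 in wt_f_144 and 692 in wt_m_112, and at most 1.58 in knockout males. Cfd was 984 in ko_f_151. For the atrial and adipocyte lists, tissue carried in single samples cannot be told apart from a difference between the sexes. The 6 lists were not rerun with 1 mouse left out.

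Nppa was higher in knockout hearts of both sexes, and atrial tissue left in some samples could raise it, since Myl7 was high in single mice. The tables argue against that as the whole cause. The 2 knockout females with Myl7 under 10 had Nppa of 7520 (ko_f_155) and 5173 (ko_f_95), a mean of 6347, 9.13 times the highest wildtype female, and the 5 knockout males, all with Myl7 under 10, had 5558, 10.04 times the highest wildtype male. Atrial tissue as a part of the value in ko_f_150, ko_f_151 and ko_f_154 stays open. An effect of the knockout on ventricular Nppa is a hypothesis that the design gives.

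The fatty acid oxidation list was lower in the difference between the sexes (camera adjusted p = 4.829e-13, adjusted p = 0.46 with an estimated correlation). In males the sarcomere median lay 0.67 above that of the list, where fewer heart muscle cells were predicted to lower both. But 10 of the 33 sarcomere genes rose in knockout males, so that list is no neutral gauge of heart muscle cells. The values also concern males alone. They therefore cannot decide whether the number of these cells plays a part in the difference. Leaving out 1 mouse gave a camera p of at most 5.3e-11, without wt_f_144. With an estimated correlation the unadjusted p was 0.031, and it passed 0.05 without ko_f_154 (0.052), wt_f_144 (0.060), ko_m_106 (0.058) or wt_m_125 (0.054), and without the mice with Myl7 of at least 500 (0.052), which was chosen after seeing the data. A difference between the sexes in how the knockout acts on these genes may account for it and stays a hypothesis, since the call depends on how the correlation between genes is set.

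Bins 33 and 34 of Gapdh were higher in knockout hearts, and a candidate explanation is that reads are shared with Gm13394, of which the mice carry different versions, as variants carried with the knockout stock could give. Gm13394 was found by a screen of 10535 genes in males for the pattern of ko_m_130, and females, whose values had not been looked at, were then tested. There the 2 knockouts with bin 33 over 2000 had Gm13394 at no more than 0.111% of the wildtype mean, as the explanation needs. Linkage to Rbm20 as a cause of calls in both sexes stays open. Within 10 Mb of it 8 of 107 genes tested were called, or 7.48% against 6.84% elsewhere (odds ratio 1.10, 95% interval 0.461 to 2.26, Fisher's exact p = 0.70). This window cannot address variants elsewhere in the genome, and Gm13394 lies on chromosome 2. The planned test, the share of the 853 calls that lay there, was void, since 107 genes cannot make up most of them. An effect of the knockout on Gapdh splicing in every knockout mouse is argued against by ko_m_130, whose Rbm20 was 263 and whose bin 33 was 33.2, 1.03 times the highest wildtype male, and by the other 9 knockouts, which lay at 1062 to 1186 or 2283 to 2514. Which variant the mice carry was not tested.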

How the results depend on the processing

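Myl7 as a covariate, and edgeR and DESeq2 on the recovered reads, were chosen only after the results were seen, and so were the tests of lists and bins in the difference. Of the genes named in females, 3206 of 3562 results kept their side of the threshold, 234 lost it and 122 gained it. In males 3196 of 3475 kept it, 214 lost it and 65 gained it, and in the difference 280 of 350 kept it and 70 gained it. None that passed in the main test or the alternative reversed direction, and the direction of results that passed in neither was not compared. With all libraries as separate samples, which treats libraries of 1 mouse as independent, 3322 genes passed in females, 3745 in males and 477 in the difference. Adding the library number as a block gave 3201, 3634 and 448. The authors' test gave 3604 in females and 3986 in males. Libraries numbered 2, among which ko_f_154 has none, gave 870 in females and 1 in the difference, and libraries numbered 1 gave 2 in the difference. An adjusted p under 0.01 left 599 genes in females, 1064 in males and 379 shared by the sexes, and a 2-fold minimum 217 and 280, by construction. In females 63.6% of these 217 were higher, against 48.95% of all calls. With Myl7 as a covariate 965 passed in males, 848 of them among the 1987. Myl7 itself differed by genotype there, with 0.769 ± 0.521 in knockout and 177 ± 292 in wildtype males. The covariate therefore takes up part of the knockout contrast, and how much of the drop this explains was not tested. For the difference, where limma gave 0 of 12462 genes and 1003 at an unadjusted p under 0.05, an adjusted p under 0.1 gave 13 and genes changed in at least 1 sex gave 98. The genes behind the 98 were picked by their change in the same mice. A large change in 1 sex also raises the difference, so that adjusted p is not a fair test. An estimated correlation within a mouse gave 147, edgeR 0 and DESeq2 45, and the cause was not tested. Leaving out each mouse gave 925 (without wt_f_141) to 1659 (without wt_f_144) genes in females, 1536 to 1880 in males and 0 to 14 in the difference, with 14 without ko_f_95, 11 without ko_m_97, 3 without wt_f_143 and 1 without ko_f_154. Of 13 lists called in females 0 passed with an estimated correlation and 5 by fry, of 13 in males 0 passed with an estimated correlation and 16 by fry, and of 7 in the difference 0 passed by either. By permutation of the list scores no list passed in females (lowest adjusted p 0.074) or in the difference (0.073). In males the matrix list (0.051), fibroblast markers and immediate early genes (each 0.059) missed the threshold. The other lists that camera called in males had 0.032 or 0.040. A log2 share change of at least 1 left 309 of 833 bins in females and 480 of 2157 in males, and an adjusted p under 0.01 left 1028 in males. TMM rescaling moved the median of all genes by less than 0.02 on the log2 scale. Size factors in place of TMM were not run, as the values were normalized, nor were tests of sex within a genotype. Depth limits which genes were tested, those with a mean of at least 10, and its effect on the calls was not tested.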

Other observations

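The scan of windows of the genome was chosen only after the results were seen. In the scan, 277 windows of 10 Mb were compared for the share of genes called in both sexes. The smallest p by Fisher's exact test was 0.0011, in the window from 150 Mb of chromosome X, where 8 of 32 genes were called (adjusted p = 0.31).

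Ano10, which encodes a membrane protein of the anoctamin family, fell in both sexes, with log2 changes of -1.37 ± 0.13 in females and -1.45 ± 0.10 in males. Its bin 3 went from 593 to 165 in females and from 533 to 143.6 in males. Ldhb-ps fell in males too, from 1471 ± 142.1 to 844 ± 276 (log2 -0.86 ± 0.17), and Ldhb had no bin past the threshold there. The knockout males differed, however. In ko_m_106 and ko_m_97 Ldhb-ps was 558 and 588 and bin 6 of Ldhb 1068 and 1223, against at most 807 in wildtype males. In the other knockout males Ldhb-ps was 834 to 1166 and bin 6 was 471 to 588. Of the female adipocyte markers, Adipoq was 338 in ko_f_151, 79.4 in ko_f_95 and 29.1 to 50.02 in the other 3 knockouts, against 3.38 to 51.99 in wildtype.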
